A study of Mus musculus with 4 samples.

How the data were processed

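The samples were mouse E14 embryonic stem cells in 2 groups of 2 libraries, control and Lx8-SINE B2 knockdown, each placed in its group by its title. Per the labels' protocols, cells were transfected with a pSuper puro vector, which expresses a short hairpin RNA and carries puromycin resistance, and were then selected with puromycin. RNA was treated with DNase, and libraries were made with the VAHTS mRNA-seq V2 kit. That kit selects mRNA, so transcripts without a poly(A) tail are measured poorly, and a difference in such transcripts can reflect the selection.

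The authors deposited raw read counts per gene, with no normalization, in 1 table. Per the submitters' processing notes, the tools were cutadapt, a trimmer, HISAT2, an aligner, and featureCounts, a read counter, and the genome build was mm10. Versions, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The treatment of such reads matters for repeat-derived transcripts, for gene families such as Zscan4 and the histones and for genes with processed pseudogenes, since leaving them out lowers the counts of near-identical copies. Without strand, reads of a gene and of its antisense partner cannot be told apart.

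The table held 36068 rows, of which 92 were spike-in rows with 0 counts in every library. These were left out, which left 35976 gene rows identified by symbol. In 27 rows the symbol had been turned into a date by a spreadsheet, and these rows held 0.15% to 0.18% of the counts of a library. They stayed in the library sizes and tests and are not named. Positions come from the RefSeq table of GRCm38.p6, the same build as mm10, in which 32501 symbols matched directly, 979 through 1 synonym and 2496 not at all. Transcript length and GC content came from GENCODE M21 for 27273 rows. Of 94 genes named by rule, 89 were found by symbol in GENCODE M21, and exons of 26 overlapped exons of another gene, in 10 cases a tested one.

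Genes were kept with filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 16209 genes and removed 19767. Libraries were scaled by TMM, with factors of 0.954 and 1.01 for the controls and 1.03 and 1.01 for the knockdown libraries. CPM in the text are scaled this way. Groups were compared with edgeR's quasi-likelihood F-test, with group as the only term, and p-values were adjusted by Benjamini-Hochberg over all tested genes. A gene was called at an adjusted p below 0.05. Log2 fold changes are knockdown over control, and the standard error is the size of the log2 fold change divided by the square root of the F statistic. Total counts were 19867689 and 19044832 in the controls and 18592224 and 16383323 in the knockdown libraries. With this depth the number of libraries, more than counting error, limits the precision for all but weakly expressed genes.

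Before the data were examined, 33 gene lists were written for embryonic stem cell states, lineages, metabolism, cell cycle, stress, signalling, silencing of repeats, RNA selection and fibroblasts as another cell type. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at a correlation estimated per list and with fry, each adjusted over the lists. Counts adjusted over the list alone apply Benjamini-Hochberg to its tested members. The genes named in the text were also set by a rule written then. It takes 8 fixed genes (Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Eno1 and Eno3), the 12 largest increases and the 12 largest decreases among called genes with a mean of at least 5 CPM whose groups do not overlap, and from each list up to 4 called members by smallest p or, with none called, the 2 most abundant members, given as values. Genes outside this rule are marked as such, and some genes that the rule takes are not reported here.

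Alternatives set before the data were examined were 3 other scalings, 2 other filters, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, the replicate number as a block, an adjusted p of 0.01, leaving out the 50 most abundant and the mitochondrial genes, leaving out each library, thinning all libraries to the shallowest, the other list tests and leaving out the top member of each list. Where 1 library was left out, the lone library of its group was assumed to vary like the other group. In these fits, and with the replicate block, 1 residual degree of freedom was left. Camera with an estimated correlation then had hardly any power, so its p-values in those fits do not show that a call fails. A correction for transcript length and GC content was added later, as were estimated correlations outside the first edgeR fit and, on DESeq2 statistics, the correlations of that fit taken as known. The whole procedure was tested on simulated counts drawn with the means and library sizes of these data, with 200 genes changed in each of 10 simulations. Of 200 simulated lists of 20 unchanged genes, 1 was called, and of 50 lists shifted by 0.5 on the log2 scale all 50 were called. Those simulated genes were independent of each other, so this does not test the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.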

Results

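The transcriptome of mouse E14 embryonic stem cells, a line derived from the inner cell mass of a 129 strain embryo, was measured by mRNA sequencing after short hairpin RNA was used against Lx8-SINE B2, an RNA named after the SINE B2 family of short interspersed repeats. The cells grew without feeder cells on gelatin in serum with LIF, the cytokine that keeps mouse embryonic stem cells undifferentiated. The deposited table of read counts per gene held 4 libraries, of which 2 came from control cells and 2 from knockdown cells. The control libraries held 19867689 and 19044832 counts, and the knockdown libraries held 18592224 and 16383323. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The word for a batch stood in the titles of the knockdown libraries alone, so a batch and the knockdown cannot be told apart. One description of transfection and puromycin selection was attached to all samples, and what vector the control cells received was not stated. The level of the targeted RNA was not analysed here, because no row of the table was found under its name.

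Libraries of a group resembled each other more than libraries of different groups. Across genes, the Pearson correlation of log2 CPM (counts scaled to library size) was 0.968 between the controls and 0.979 between the knockdown libraries, against 0.944 to 0.959 across groups. The first principal component held 56.7% of the variance and separated the groups. The second held 27.6% and separated the controls, at 47.9 and -42.9, with the knockdown libraries between them at -5.47 and 0.502. The counts within each pair differed by far more than sampling noise, with a chi-square per degree of freedom of 46.9 for the controls and 21.8 for the knockdown libraries, so each library was counted as 1 replicate. The biological coefficient of variation, edgeR's name for the spread between libraries of a group, was 24.9%.

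The only comparison in the design asked how the transcriptome differed between knockdown and control cells. Transcripts of glycolytic enzymes and of other hypoxia-inducible genes were lower in the knockdown cells, as were transcripts of cholesterol synthesis and of the NODAL inhibitors Lefty1 and Lefty2. Transcripts of p53 targets and of YAP targets were higher. These list calls were made with camera at a preset correlation between genes. With an estimated correlation the adjusted p was 0.264 for the glycolysis, hypoxia, cholesterol and p53 lists. It was 0.367 for the NODAL list and 0.498 for the YAP list, and the rotation test fry called 0 lists. Estimated correlations were above the preset 0.01 for the glycolysis (0.208), hypoxia (0.0337), cholesterol (0.0435) and YAP (0.363) lists. They were higher still for the ribosomal protein and histone lists, at 0.513 and 0.726. For these lists the preset p-values rest on a lower correlation than was estimated from these libraries. The estimates for the p53 and NODAL lists, 0.0044 and -0.0398, were below the preset 0.01. The loss of these 2 calls therefore does not come from a higher correlation. With an estimated correlation camera tests on the 2 residual degrees of freedom of these libraries. The pluripotency factors Pou5f1, Sox2 and Nanog were not called in either direction. Of 16209 genes tested with edgeR's quasi-likelihood test, 232 passed a Benjamini-Hochberg adjusted p of 0.05, with 142 higher and 90 lower in the knockdown cells. At a change of at least 2-fold, 224 genes remained, of which 141 were higher and 83 lower. In all 232 called genes, both knockdown libraries lay on the same side of both controls. A gene that passes the test is nearly bound to show this. The groups were also apart in this way in 8412 of the 16209 tested genes, where chance gives 33.3% with 2 libraries against 2. The number of calls depended on single libraries: it was 587 without control replicate 1, 349 without control replicate 2, 386 without knockdown replicate 1 and 153 without knockdown replicate 2. Of the 232 genes, 92 were called in all 4 of these fits, 44 in 3, 64 in 2, 27 in 1 and 5 in 0, and none changed direction.

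**Figure D1:**
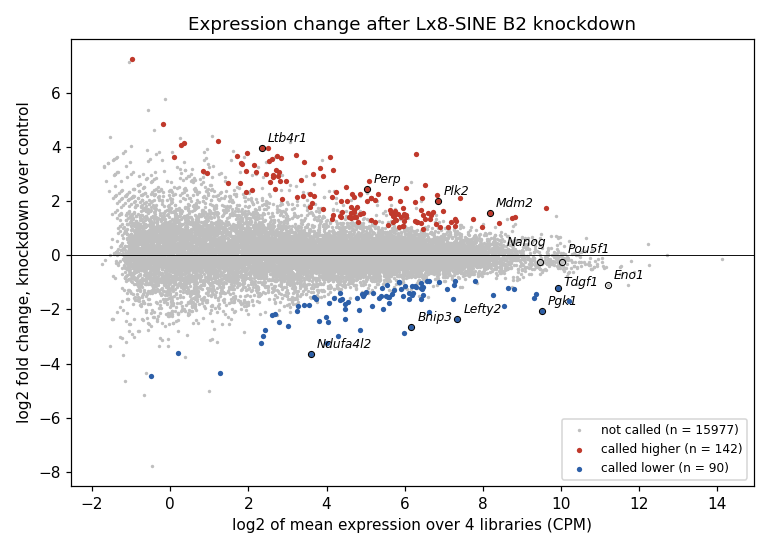
Log2 fold change of knockdown over control against the log2 of the mean expression in CPM, one point per tested gene, with 142 genes called higher in red, 90 called lower in blue and 15977 not called in grey (edgeR, adjusted p of 0.05, 2 libraries per group). Pgk1, Bnip3, Lefty2 and Ndufa4l2 lie among the genes called lower, Mdm2, Plk2 and Perp among those called higher, and Pou5f1, Nanog and Eno1 were not called.

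Glycolysis genes fell as a list. All gene lists described here were fixed before the data were examined. Members named only for a count adjusted over the list alone were chosen after their values were seen. Each list was tested with camera at a preset correlation between genes of 0.01. Of 23 tested genes for glycolytic enzymes and for glucose or lactate transporters, 8 fell and 0 rose at the threshold over all genes, and 20 fell when adjusted over the list alone. The glucose transporter genes Slc2a1 and Slc2a3, named after their values were seen, passed neither way, with log2 fold changes of -0.31 and -0.37. The median log2 fold change was -1.09, and the list was called lower with a camera adjusted p of 1.06e-29. The adjusted p was 0.264 with an estimated correlation. Pgk1, the phosphoglycerate kinase gene on chromosome X from 106187100 to 106203699 (mm10), fell 4.15-fold, from 1170 ± 64.9 CPM (SD, n = 2) to 282 ± 5.97 CPM (SD, n = 2). Its log2 fold change was -2.05 with a standard error of 0.18 and an edgeR adjusted p of 0.0097. Aldoc, an aldolase gene on chromosome 11 from 78323073 to 78327781, fell 9.40-fold, from 29.2 ± 3.69 to 3.12 ± 0.93 CPM (edgeR adjusted p = 0.0097). Slc16a3, which encodes a lactate exporter, fell 4.22-fold (edgeR adjusted p = 0.0173). Pfkp, a phosphofructokinase gene, fell 2.96-fold (edgeR adjusted p = 0.0153), but was not called without knockdown replicate 2, where its log2 fold change was -1.52. The other called members were Ldha, Tpi1, Ldhb and Pfkl, with log2 fold changes of -1.70, -1.86, -1.61 and -1.47, which are named after their values were seen. Eno1, the main enolase gene of these cells at 3175 ± 689 CPM in the controls and 1494 ± 249 CPM in the knockdown libraries, had a log2 fold change of -1.09 with a standard error of 0.24 and did not pass (edgeR adjusted p = 0.0666). It did pass with DESeq2, with the likelihood ratio test, with either other filter on low counts and without control replicate 2, at -1.35. It did not pass without control replicate 1 at -0.85, without knockdown replicate 1 at -0.93 or without knockdown replicate 2 at -1.27. The muscle enolase gene Eno3 had a log2 fold change of -0.41 (edgeR adjusted p = 0.62), which was 0.22 without control replicate 1, -0.91 without control replicate 2, -0.06 without knockdown replicate 1 and -0.89 without knockdown replicate 2. Several of these genes have processed pseudogenes or near-identical copies, among them Eno1, Pgk1 and Ldha, so their counts are uncertain to the extent that reads were shared.

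Hypoxia-inducible genes fell as a list, with a median log2 fold change of -0.77 over 18 tested genes and a camera adjusted p of 4.19e-10. The adjusted p was 0.264 with an estimated correlation. Over all genes 3 fell, and adjusted over the list alone 12 fell and 1, Ddit4, rose. Bnip3, a mitophagy receptor gene on chromosome 7 from 138890836 to 138909506, fell 6.25-fold, from 124 ± 28.7 to 19.8 ± 0.53 CPM (SD, n = 2 each), with a log2 fold change of -2.64, a standard error of 0.22 and an edgeR adjusted p of 0.0097. Egln3, a prolyl hydroxylase gene that HIF induces, fell 4.89-fold, and Ndrg1 fell 3.52-fold. Ndufa4l2, a hypoxia-inducible mitochondrial gene that is in no list, showed the largest decrease among the genes named by rule, 12.5-fold, from 22.4 ± 2.82 to 1.80 ± 0.55 CPM (edgeR adjusted p = 0.0097).

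In the lists for mitochondrial pathways 0 members were called. Pyruvate dehydrogenase and TCA cycle genes had a median log2 fold change of -0.29 over 21 genes (camera adjusted p = 0.0019, and 0.60 as the adjusted p with an estimated correlation). Nuclear genes of the respiratory chain had a median of -0.25 over 35 genes (camera adjusted p = 5.37e-04, and 0.60 as the adjusted p with an estimated correlation), which was -0.41 without control replicate 2. After the correction for transcript length and GC content, added later, it was -0.18. Abundant members were not called, with Atp5b and Atp5a1 at -0.47 and -0.57 and Cs at 0.06, a value that ranged from -0.18 without knockdown replicate 2 to 0.26 without knockdown replicate 1. The 13 mRNAs of the mitochondrial genome had a median of -0.25 (camera adjusted p = 0.0268, and 0.62 as the adjusted p with an estimated correlation). This list was not called without control replicate 2, where its median was -0.17, or without knockdown replicate 1, where it was -0.12, and its median was -0.71 without knockdown replicate 2. Its call was also lost without the member with the smallest p, at -0.22. Its most abundant members, COX1 and ND1, had log2 fold changes of -0.68 and -0.25 and were not called. COX1 depended on the control kept: it was called lower without control replicate 1 at -1.16 and was at -0.01 without control replicate 2. ND1 ranged from -0.43 without knockdown replicate 2 to -0.09 without knockdown replicate 1. Mitochondrial mRNAs took 0.66% and 1.13% of the counts in the controls and 0.60% and 0.72% in the knockdown libraries.

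**Figure D2:**
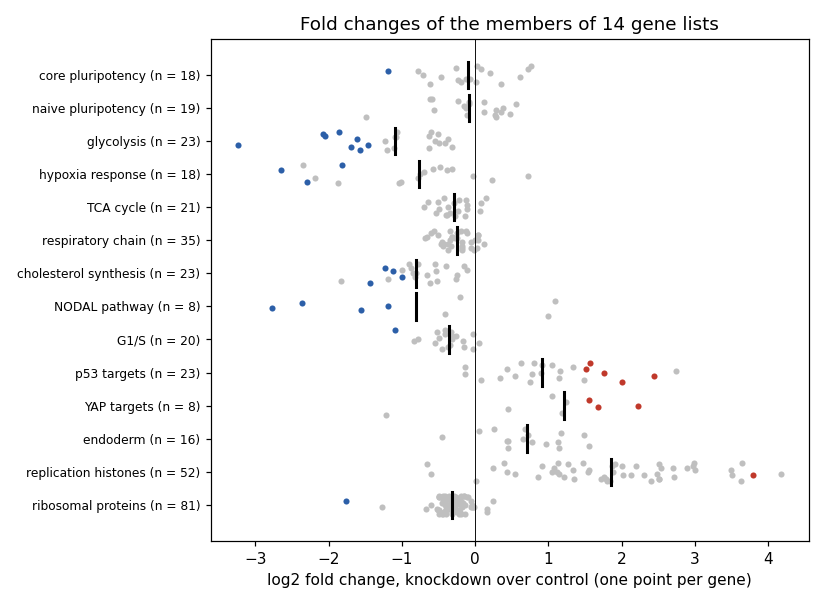
Log2 fold change of knockdown over control for each tested member of 14 gene lists, one point per gene, with members called higher in red, called lower in blue and not called in grey, and a black bar at the median of each list (edgeR, 2 libraries per group). The medians are -1.09 for glycolysis, -0.81 for cholesterol synthesis, 0.91 for p53 targets and -0.10 for core pluripotency.

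Targets of the tumour suppressor p53 were higher. Of 23 tested genes, 5 rose over all genes (Plk2, Perp, Mdm2, Phlda3 and Ddit4l, the last of which is outside the naming rule and was chosen after its values were seen), 17 rose when adjusted over the list alone and 0 fell. The median log2 fold change was 0.91, with a camera adjusted p of 9.71e-18 and an adjusted p of 0.264 with an estimated correlation. Mdm2, which encodes the ubiquitin ligase that degrades p53 and lies on chromosome 10 from 117688875 to 117710758, rose 2.97-fold, from 146 ± 1.08 to 432 ± 36.3 CPM (SD, n = 2 each), with a log2 fold change of 1.57, a standard error of 0.17 and an edgeR adjusted p of 0.012. Plk2, a polo-like kinase gene on chromosome 13 from 110395044 to 110400844, rose 4.02-fold, from 45.8 ± 4.29 to 184 ± 23.4 CPM (edgeR adjusted p = 0.0097). Perp, a p53 effector at cell junctions, rose 5.41-fold and Phlda3, an inhibitor of AKT, rose 2.84-fold. These 4 genes were called in each fit that left out 1 library. Targets of the Hippo pathway coactivator YAP had a median log2 fold change of 1.22 over 8 genes (camera adjusted p = 8.84e-08, and 0.498 as the adjusted p with an estimated correlation). Over all genes 3 rose, and adjusted over the list alone 6 rose and 1, Axl, fell. Ptpn14, a phosphatase gene that feeds back on YAP, rose 4.67-fold, from 40.2 ± 12.2 to 188 ± 32.1 CPM (edgeR adjusted p = 0.0134). The matricellular genes Ctgf and Cyr61 rose 3.21-fold and 2.94-fold. Ctgf was not called without control replicate 2 or knockdown replicate 1, where its log2 fold changes were 1.54 and 1.26. Cyr61 was not called without control replicate 2 or knockdown replicate 2, where its values were 1.21 and 1.40, nor with any of the 3 other scalings.

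Cholesterol synthesis genes and targets of SREBP2, the transcription factor that controls them, had a median log2 fold change of -0.81 over 23 genes (camera adjusted p = 2.59e-14, and 0.264 as the adjusted p with an estimated correlation). Over all genes 4 fell, adjusted over the list alone 18 fell, and 0 rose either way. Dhcr7, which encodes the last reductase of the pathway, fell 2.70-fold, from 75.1 ± 4.69 to 27.9 ± 2.42 CPM (SD, n = 2 each, edgeR adjusted p = 0.0197). The farnesyl diphosphate synthase gene Fdps fell 2.34-fold, the lanosterol demethylase gene Cyp51 fell 1.99-fold and Insig1, a sterol sensor gene, fell 2.17-fold. None of these calls held without knockdown replicate 2, where the log2 fold changes were -1.34, -1.21, -1.03 and -0.95 in that order. Fdps at -1.24 and Cyp51 at -0.96 were also not called without knockdown replicate 1, nor was Insig1 at -1.01 without control replicate 2.

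Genes of the NODAL pathway moved both ways. Over all genes 4 of 8 fell, and adjusted over the list alone the same 4 fell and 2 rose, Nodal itself and Pmepa1. The median log2 fold change was -0.80, with a camera adjusted p of 3.17e-04 and an adjusted p of 0.367 with an estimated correlation. The median was -0.41 without the member with the smallest p. Among the genes that fell were Lefty1 and Lefty2, which encode secreted NODAL inhibitors, and the NODAL coreceptor gene Tdgf1. Lefty2, on chromosome 1 from 180893108 to 180899107, fell 5.15-fold, from 272 ± 97.7 to 52.8 ± 21.5 CPM (SD, n = 2 each, edgeR adjusted p = 0.0257). The neighbouring and near-identical Lefty1 fell 2.93-fold, and reads shared between these genes would make both values uncertain. Tdgf1 fell 2.29-fold, from 1342 ± 297 to 587 ± 21.8 CPM (edgeR adjusted p = 0.0438). Without knockdown replicate 2 the calls of Lefty1 at -1.41 and Tdgf1 at -1.23 were lost, and that of Tdgf1 at -1.16 also without knockdown replicate 1.

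Pluripotency genes as lists were not called. General pluripotency factors had a median log2 fold change of -0.10 over 18 genes (camera adjusted p = 0.295), with Tdgf1 as the 1 called member. That list was called lower without control replicate 2, where its median was -0.28 (camera adjusted p = 0.0236, and 0.568 as the adjusted p with an estimated correlation), and its median was 0.05 without control replicate 1. Naive pluripotency factors had a median of -0.08 over 19 genes with 0 called (camera adjusted p = 0.491) and 1, Tcl1, lower when adjusted over the list alone. The naive median ranged from -0.07 without knockdown replicate 1 to 0.10 without control replicate 1. Targets of LIF and STAT3 had a median of -0.20 (camera adjusted p = 0.192), which became -0.48 and was called without control replicate 2 (adjusted p = 0.564 with an estimated correlation) and was -0.04 without control replicate 1. Pou5f1, which encodes OCT4 and lies on chromosome 17 from 35506032 to 35510777, was at 1119 ± 194 CPM in the controls and 949 ± 65.3 CPM in the knockdown libraries (SD, n = 2 each), a log2 fold change of -0.24 with a standard error of 0.20 (edgeR adjusted p = 0.556). Sox2 had a log2 fold change of -0.07 with a standard error of 0.22, Nanog one of -0.27 with a standard error of 0.24, Klf4 one of -0.09 with a standard error of 0.37, Esrrb one of 0.13 with a standard error of 0.18 and Zfp42 one of -0.12 with a standard error of 0.21. None of these was called. Klf4 was at 0.44 without knockdown replicate 2 and at -0.93 without knockdown replicate 1, so its value averages 2 libraries that lie on either side of the controls. Over the 4 fits that left out 1 library, Pou5f1 ranged from -0.46 (without control replicate 2) to -0.05 (without control replicate 1), Sox2 from -0.39 to 0.24 and Zfp42 from -0.37 to 0.10 in the same order. Nanog ranged from -0.54 without control replicate 1 to 0.02 without control replicate 2, and Esrrb from 0.01 without control replicate 2 to 0.21 without knockdown replicate 1.

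**Figure D3:**
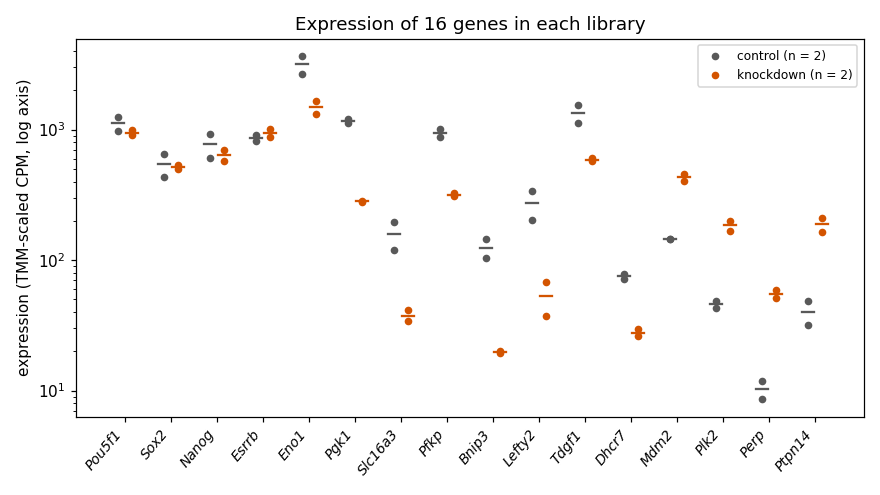
Expression of 16 genes in each library, in CPM scaled by TMM on a log axis, with points for the 2 control libraries in grey and the 2 knockdown libraries in orange and a bar at each group mean. The libraries of the groups overlap or nearly meet for Pou5f1, Sox2, Nanog and Esrrb, while Pgk1, Slc16a3, Pfkp, Bnip3, Mdm2, Plk2, Perp and Ptpn14 are clearly apart.

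Among lineage lists, primitive and definitive endoderm genes were higher, with a median log2 fold change of 0.70, 15 of 16 genes positive and 0 called (camera adjusted p = 0.004, and 0.60 as the adjusted p with an estimated correlation). The median was 0.41 without knockdown replicate 1, 1.12 without knockdown replicate 2 and 1.08 without control replicate 2. After the correction for transcript length and GC content, added later, the median of the endoderm list was 0.51. Its most abundant members were the laminin gene Lamc1 at 0.68 and Sparc at 0.45. Lamc1 was called higher without control replicate 1 at 1.17 and was at 0.27 without control replicate 2, and Sparc ranged from -0.15 without knockdown replicate 2 to 0.87 without knockdown replicate 1. Primed epiblast genes had a median of -0.07 (camera adjusted p = 0.38), and Fgf15, an epiblast growth factor gene, fell 5.49-fold, a call lost without knockdown replicate 2 at -2.18. The direction of this list depended on the control kept: it was called lower without control replicate 2 at -0.53 (adjusted p = 0.568 with an estimated correlation), while its median was 0.73 without control replicate 1, where it was not called, and 0.0450 without knockdown replicate 2. Neuroectoderm genes had a median of 0.21 (camera adjusted p = 0.243), and Neurod1, a neurogenic transcription factor gene, rose 4.23-fold, a call lost without control replicate 2 at 1.94 and without knockdown replicate 2 at 2.02. The list itself was called higher without knockdown replicate 2 at 0.45 (adjusted p = 0.689 with an estimated correlation), and its median was 0.05 without knockdown replicate 1. Primitive streak and mesoderm genes had a median of 0.27 (camera adjusted p = 0.437) and trophectoderm genes a median of 0.49 (camera adjusted p = 0.227), with 0 called in either list. Adjusted over the list alone, 3 genes of the former rose (Kdr, Wnt3 and Evx1) and 2 fell (Bmp4 and Cdx1), and 2 of the latter rose (Gata3 and Fgfr2). Trophectoderm genes were called higher without knockdown replicate 1 at 0.51 (adjusted p = 0.824 with an estimated correlation), but their median was -0.05 without knockdown replicate 2 and 0.10 without control replicate 2. The median of the primitive streak and mesoderm list ranged from -0.11 without knockdown replicate 2 to 0.37 without control replicate 2. The most abundant members of these lists had log2 fold changes of -1.11 for Bmp4, 0.24 for Eomes, -0.01 for Tfap2c and 0.51 for Krt8. Krt8 was at 1.17 without knockdown replicate 1, -0.73 without knockdown replicate 2, 0.10 without control replicate 1 and 1.02 without control replicate 2. Bmp4 was called lower without control replicate 2 at -1.58 and was at -0.51 without control replicate 1, Eomes ranged from -0.05 without knockdown replicate 2 to 0.48 without knockdown replicate 1, and Tfap2c from -0.14 without control replicate 2 to 0.07 without control replicate 1. Fibroblast markers, a check for another cell type, had a median of -0.20 but a mean of 0.06, and were not called (camera adjusted p = 0.97), with Fn1 and Vim both at -0.20. Their median ranged from -0.26 without knockdown replicate 1 to 0.06 without control replicate 1, Vim from -0.52 without control replicate 2 to 0.13 without control replicate 1, and Fn1 from -0.35 without control replicate 2 to -0.08 without knockdown replicate 2. Adjusted over the list alone, 3 of them rose (Fbn1, S100a6 and Twist1) and 2 fell (Thy1 and Pdgfrb). With DESeq2, which was given every gene with at least 1 count, the fibroblast median was 0.74 and the list was again not called.

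Genes of the G1/S transition and DNA replication were lower, with a median log2 fold change of -0.36 over 20 genes (camera adjusted p = 3.46e-05, and 0.60 as the adjusted p with an estimated correlation). Ccne1, the cyclin E1 gene, was the 1 member that fell over all genes, 2.13-fold, and 3 fell when adjusted over the list alone (Ccne1, Pcna and Gins2). The Ccne1 call was lost without knockdown replicate 1 at -1.07 and without knockdown replicate 2 at -1.11. The G2/M genes had a median of -0.22 over 21 genes with 0 called and 1, Kif23, lower when adjusted over the list alone (camera adjusted p = 0.0051, and 0.60 as the adjusted p with an estimated correlation), with Top2a at -0.71 and Mki67 at -0.15. Top2a was called lower without control replicate 1 at -0.92, and Mki67 ranged from -0.41 without control replicate 1 to 0.11 without control replicate 2. Ribosomal protein genes had a median of -0.32 over 81 genes (camera adjusted p = 1.06e-08, and 0.60 as the adjusted p with an estimated correlation), which was -0.17 without control replicate 1 and -0.48 without control replicate 2. After the correction for transcript length and GC content, added later, it was -0.24. The 1 called member was Rpl39, which fell 3.39-fold and has many processed pseudogenes. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median of 1.85 over 52 genes (camera adjusted p = 7.71e-15, and 0.60 as the adjusted p with an estimated correlation). Over all genes 1 rose, the linker histone gene Hist1h1b, and 30 rose when adjusted over the list alone. The Hist1h1b call was lost without either control, at 3.53 and 4.04, and without knockdown replicate 2, at 2.86. The summed level of the list was 103 and 130 CPM in the controls and 255 and 833 CPM in the knockdown libraries, and the median was 0.93 without knockdown replicate 2.

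Outside the lists, the largest increases among genes named by rule were those of Ltb4r1 and Ltb4r2, neighbouring genes for leukotriene B4 receptors on chromosome 14, at 15.6-fold and 15.5-fold. Ltb4r1, from 55765962 to 55768492, went from 0.60 ± 0.19 to 9.51 ± 2.12 CPM (SD, n = 2 each), with a log2 fold change of 3.96, a standard error of 0.47 and an edgeR adjusted p of 0.0155. The prostaglandin synthase gene Ptgs2 rose 11.1-fold, the sorting nexin gene Snx20 rose 12.8-fold, the cartilage matrix gene Matn1 rose 8.76-fold, the neuropeptide precursor gene Vgf rose 7.83-fold, Fam212b rose 7.67-fold, the homeobox gene Nkx2-9 rose 7.60-fold and Cemip, which takes part in hyaluronan breakdown, rose 7.38-fold. Control means of these genes were low, from 0.94 CPM for Ptgs2 to 3.66 CPM for Matn1, so the sizes of the increases are uncertain. The sizes for Snx20 and Matn1 depended on the control kept, with log2 fold changes of 4.90 and 4.22 without control replicate 1 and of 2.97 and 2.46 without control replicate 2, all called. Plcd4, a phospholipase C gene, rose 9.25-fold, but 29.8% of its exon bases overlap Zfp142 on the opposite strand, so its value is uncertain. Exons of untested genes overlap 33.0% of the exon bases of Phlda1, 29.4% of Notum and 26.7% of Fdps. For Fgf15 and Bnip3 such an overlap covers 24.9% and 22.3%, so the values of these genes are uncertain too. Ube2dnl1 rose 12.6-fold, a call lost without control replicate 1 at 3.87, without control replicate 2 at 3.41 and without knockdown replicate 2 at 2.60, and its value was 4.26 without knockdown replicate 1. Pramel6 rose 12.4-fold, a call lost without control replicate 1 at 3.72 and without control replicate 2 at 3.50, and its log2 fold change was 2.39 without knockdown replicate 2 and 4.29 without knockdown replicate 1.

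Among the decreases outside the lists, the proton pump subunit gene Atp6v0a4 fell 9.54-fold, the collagen crosslinking enzyme gene Loxl2 fell 7.80-fold, the protease inhibitor gene A2m fell 7.36-fold, Ndrg2 fell 6.73-fold, the glutamate transporter gene Slc1a3 fell 6.18-fold and the villin-like gene Vill fell 5.47-fold. A2m, on chromosome 6 from 121636165 to 121679238, went from 112 ± 32.2 to 15.2 ± 0.50 CPM (SD, n = 2 each, edgeR adjusted p = 0.0097). Slfn9, a schlafen family gene, fell 5.38-fold, a call lost without control replicate 1 at -1.80 and without knockdown replicate 2 at -2.12.

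The lists for interferon and sensing of double-stranded RNA, silencing of repeats, the ATF4 response, the unfolded protein response and heat shock were not called. Interferon-stimulated genes and sensors of double-stranded RNA had a median log2 fold change of -0.02 with 0 members called (camera adjusted p = 0.277), and Stat2 and Ddx58 were at -0.61 and -0.01. The median of this list ranged from -0.47 without knockdown replicate 2 to -0.03 without knockdown replicate 1, and Ddx58 from -0.49 without control replicate 2 to 0.59 without control replicate 1. Genes that silence transposable elements had a median of -0.04 (camera adjusted p = 0.243). After the correction for transcript length and GC content, added later, it was -0.17 and the list was not called (camera adjusted p = 0.14). The chromatin assembly gene Chaf1b fell 2.17-fold, a call lost without knockdown replicate 1 at -1.15 and without knockdown replicate 2 at -1.10, and the list was called lower without control replicate 2 at -0.29 (adjusted p = 0.564 with an estimated correlation), while its median was 0.09 without control replicate 1. In the ATF4 and amino acid response list (median 0.17, camera adjusted p = 0.295) the stress transcription factor gene Atf3 rose 6.72-fold and the serine synthesis gene Phgdh fell 3.03-fold. Adjusted over the list alone 5 rose (Atf3, Atf4, Ddit3, Cars and Sesn2) and 1 fell. The median of this list ranged from 0.04 without control replicate 2 to 0.26 without control replicate 1, and was 0.10 without knockdown replicate 1. The Atf3 call was lost in each fit that left out 1 control library, at 2.54 and 2.93, and without knockdown replicate 2 at 1.95. Endoplasmic reticulum chaperones and the unfolded protein response had a median of 0.06 and a mean of 0.01, against a lower direction in the test (camera adjusted p = 0.99), with Calr at 0.10 and Hspa5 at 0.07. The median of this list ranged from -0.05 without control replicate 2 to 0.13 without control replicate 1, Calr from -0.01 without knockdown replicate 2 to 0.20 without knockdown replicate 1, and Hspa5 from -0.03 without control replicate 1 to 0.12 without control replicate 2. Cytosolic heat shock genes had a median of 0.35 (camera adjusted p = 0.0723), with 0 called and 3 higher when adjusted over the list alone (Hspb8, Hsph1 and Dnajb1), with Hspa8 at 0.40 and Hsp90ab1 at 0.01, and were called higher without control replicate 2 at 0.34 and without knockdown replicate 1 at 0.46. With an estimated correlation the adjusted p was 0.60 with all libraries. The list was not called that way without control replicate 2 or knockdown replicate 1 either, but that test has hardly any power there. Hsp90ab1 ranged from -0.15 without control replicate 2 to 0.13 without control replicate 1. The list was also called higher with DESeq2 at 0.32 and at 0.38 after a correction for transcript length and GC content, which was chosen after seeing the data. With an estimated correlation the adjusted p was 0.606 after that correction, and 0.137 on DESeq2 statistics with the correlation of the edgeR fit.

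Signalling lists other than NODAL and YAP were not called. In the immediate early and ERK feedback list (median 0.15, camera adjusted p = 0.2) Phlda1 rose 4.45-fold and Jun, an AP-1 transcription factor gene, rose 3.30-fold. Phlda1 was not called without control replicate 2 at 1.83 or knockdown replicate 2 at 1.68, Jun was not called without knockdown replicate 2 at 1.63, and the list was called higher without control replicate 1 at 0.50 (adjusted p = 0.671 with an estimated correlation), with a median of -0.12 without control replicate 2. Targets of WNT had a median of -0.34 (camera adjusted p = 0.243), with Tcf7 at -0.23 and Notum at 0.49. Notum was at -0.37 without knockdown replicate 1, 1.02 without knockdown replicate 2, 1.05 without control replicate 1 and 0.04 without control replicate 2. Tcf7 was at -0.03 without control replicate 1, -0.46 without control replicate 2, -0.42 without knockdown replicate 1 and -0.07 without knockdown replicate 2. The list median was -0.73 without knockdown replicate 1, -0.07 without knockdown replicate 2 and -0.16 without control replicate 1. Targets of BMP had a median of 0.22 (camera adjusted p = 0.192), with 1 gene, Id3, higher when adjusted over the list alone, with Smad7 at -0.21 and Id1 at 0.43, and were called higher without control replicate 1 at 0.68 (adjusted p = 0.705 with an estimated correlation), with a median of 0.02 without control replicate 2. Id1 ranged from 0.02 without control replicate 2 to 0.91 without control replicate 1, and Smad7 from -0.46 without knockdown replicate 2 to -0.0022 without knockdown replicate 1.

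In some lists the direction or the size depended on which control was used. Genes of the 2-cell-like state, a rare state of these cultures marked by the Zscan4 cluster, had a median log2 fold change of 0.36 and were not called (camera adjusted p = 0.2). The summed level of this list was 116 CPM in control 1, 1734 CPM in control 2, 628 CPM in knockdown 1 and 724 CPM in knockdown 2. The list was called lower without control replicate 1 at -0.49 and higher without control replicate 2 at 2.51. With an estimated correlation the adjusted p was 0.624 and 0.564 in these 2 fits and 0.822 with all libraries. It was also called higher with limma-voom, at 0.96 (adjusted p = 0.701 with an estimated correlation). Zscan4f, at 203 ± 260 CPM in the controls and 108 ± 9.84 CPM in the knockdown libraries (SD, n = 2 each), and Zscan4c are near-identical copies with uncertain counts. Both were called lower without control replicate 1, at -1.84 and -1.57, and higher without control replicate 2, at 2.44 and 2.51. Germline genes had a median of -0.15, against a higher direction in the test (camera adjusted p = 0.99), and were called lower without control replicate 1 at -0.48 and higher without control replicate 2 at 0.58 (adjusted p = 0.7235 and 0.639 with an estimated correlation). The germline median was 0.01 without knockdown replicate 1 and -0.42 without knockdown replicate 2. Dazl and Mov10l1 in that list had log2 fold changes of 0.34 and -1.10. Mov10l1 was called lower without control replicate 1 at -1.68 and was at -0.17 without control replicate 2. Dazl was at -0.12 without control replicate 1, 0.96 without control replicate 2, 0.84 without knockdown replicate 1 and -0.41 without knockdown replicate 2. Imprinted genes were called higher, with a median of 0.66 over 20 genes (camera adjusted p = 0.0013, and 0.60 as the adjusted p with an estimated correlation), which was 1.07 without control replicate 1 and 0.20 without control replicate 2. It was 0.41 after the correction for transcript length and GC content. Over all genes 0 imprinted genes were called, and adjusted over the list alone 7 rose and 2 fell, Phlda2 and Slc38a4. Peg10 had a log2 fold change of 1.46 (edgeR adjusted p = 0.0556) and Meg3, at 554 ± 499 CPM in the controls and 866 ± 3.65 CPM in the knockdown libraries, one of 0.64. Peg10 was called higher without control replicate 1 at 1.84 and without knockdown replicate 1 at 1.72, and Meg3 was called higher without control replicate 1 at 2.10 and was at -0.12 without control replicate 2.

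In each list for which no such count was given, as many genes passed when adjusted over the list alone as over all genes. With the total count as the only scaling, the calls of Tdgf1, Cyp51, Insig1, Jun, Chaf1b, Hist1h1b, Atf3, Cyr61, Slfn9 and Ube2dnl1 were lost, and those of Atf3, Insig1 and Cyr61 also with the 2 other scalings and that of Slfn9 with the upper quartile.

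Of the 33 lists, 15 were called with the preset correlation, 5 higher and 10 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.264. The rotation test fry also called 0 lists, with a smallest adjusted p of 0.0629, and its test for change in either direction called 19. In data simulated from these libraries with 200 changed genes, 23.6% of genes changed by 2-fold and 72.3% of genes changed by 4-fold were called. Most 2-fold changes were thus missed in that setting with 2 libraries per group. Of the simulated calls 10.6% were of unchanged genes, more than an adjusted p of 0.05 allows. In the data 3174 of 16209 tested genes had an unadjusted edgeR p below 0.05. The share detected depends on how many genes change, so the simulated shares need not hold for these data.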

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

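The correction for transcript length and GC content, and every estimated correlation outside the first edgeR fit, were chosen after seeing the data, and every other alternative was set before. All 232 called genes that were tested in an alternative kept their direction in it. Against 232 calls, 142 higher, 90 lower and 224 at 2-fold or more, the counts stayed within 1.5 times with median-of-ratios size factors (196), upper quartile scaling (188), a mean of at least 5 CPM (299), thinning to the shallowest library (258), limma-voom (241) and without the most abundant and mitochondrial genes (243). With the total count alone 57 genes were lower. Without a filter on low counts 1717 genes were called, 996 higher, 721 lower and 1244 at 2-fold or more. The likelihood ratio test called 1310, 796 higher, 514 lower and 1024 at 2-fold or more, and DESeq2 called 1074, 591 higher, 483 lower and 806 at 2-fold or more. At an adjusted p of 0.01 there were 17 calls, 11 higher, 6 lower and 17 at 2-fold or more. After the length and GC correction 347 genes were called and 157 were lower. Of 52 named genes that were called, 43 were lost at that stricter threshold, 10 with the total count, 6 with limma-voom, 4 with the upper quartile, 3 with median-of-ratios factors and 2 after the correction. The cause of these differences was not tested, except that a stricter threshold can only call fewer.

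With the replicate number as a block, the replicate block fit called 656 genes, 428 higher, 228 lower and 580 at 2-fold or more. The correlation of same-numbered libraries' deviations from their group means was -0.06 over 11055 genes. No pairing thus showed over these genes as a whole, which does not exclude one in some genes. Among the lists, the block added calls of the 2-cell-like list (adjusted p = 0.0025, median 0.91) and the heat shock list (adjusted p = 0.0389, median 0.36), both higher, and changed no other list call. With an estimated correlation in that fit neither was called (adjusted p = 0.7147 and 0.7145). The glycolysis list was at 0.7145 there too, as that test has hardly any power with 1 residual degree of freedom.

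Leaving out 1 library gave 153 to 587 calls, 108 to 389 higher, 45 to 198 lower and 153 to 506 at 2-fold or more, with the lowest counts without knockdown replicate 2 and the highest without control replicate 1. The glycolysis list stayed called lower, with medians of -1.31 to -0.90. The core pluripotency list ranged from -0.28, called without control replicate 2, to 0.051 without control replicate 1. Without control replicate 1 the lists of the 2-cell-like state (-0.49) and the germline (-0.48) turned lower, Zscan4f (-1.84) and Zscan4c (-1.57) were called lower, and without control replicate 2 the germline list (0.58), Zscan4f (2.44) and Zscan4c (2.51) were higher and called, which follows from the difference between the controls in these genes. Without control replicate 2, 8 lists were called higher.

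With an estimated correlation and with fry, 0 lists were called, 0 higher and 0 lower. The glycolysis list had the same median of -1.09 in both, with adjusted p of 0.264 and 0.113. In the fits that left out 1 library 0 lists were called with an estimated correlation. That test has hardly any power with 1 residual degree of freedom, so this does not show that the calls fail. On DESeq2 statistics, taking the correlations of the edgeR fit as known, 9 lists were called, 4 higher and 5 lower. Among them were glycolysis (median -1.12, adjusted p = 1.41e-11) and neuroectoderm, which the first fit did not call (median 0.50, adjusted p = 0.0277). The fibroblast list had no value. Taking the correlations as known leaves out the error of correlations estimated from 4 libraries. Each of these tests rests on 2 libraries per group, and fry does not compare a list with other genes.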

Other observations

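Fatty acid synthesis, MYC-linked ribosome biogenesis and the pentose phosphate pathway were examined in lists written after the first results were seen, and 0 of their members were called. Genes named in these observations are outside the naming rule and were chosen after their values were seen, unless the report names them too. Of 12 fatty acid synthesis genes, 10 had negative log2 fold changes, with a median of -0.35 and 0 called (limma's camera, adjusted p = 0.0048). The adjusted p was 0.145 with an estimated correlation. Fads2, a desaturase gene, was at -0.86 and Acaca, which encodes the enzyme that makes malonyl-CoA, at -0.65. Of 22 MYC-linked ribosome biogenesis genes, 20 were negative with a median of -0.28 and 0 called (camera adjusted p = 0.0082, and 0.358 as the adjusted p with an estimated correlation), with the nucleolar genes Npm1 at -0.46 and Ncl at -0.40. The 8 pentose phosphate genes had a median of -0.17 (camera adjusted p = 0.169), with Tkt at -0.79 and Rpe at 0.58.

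The transcripts of the regulators themselves were not called. Trp53 had a log2 fold change of 0.19 with a standard error of 0.18, Hif1a one of 0.27 with a standard error of 0.18 and Myc one of 0.02 with a standard error of 0.28. Cdkn1a, the p53 target that encodes the p21 inhibitor of cell cycle kinases, was at 1.49 (edgeR adjusted p = 0.0543). The second principal component separated the controls from each other. Genes of the 2-cell-like state and of an imprinted cluster were among those that differed between them. The 5 Zscan4 genes summed to 62.5 CPM in control 1 and 1320 CPM in control 2, against 337 and 409 CPM in the knockdown libraries. Meg3 was at 907 CPM in control 1 and 201 CPM in control 2, against 868 and 863 CPM in the knockdown libraries, and Rian, from the same cluster, was at 596 and 184 CPM against 691 and 558 CPM.

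In the 3 patterns weighed next, both tests of the histone pattern and the length and GC correction were chosen only after the results were seen, and the additional hypoxia and p53 lists left out genes already seen to be called. Intervals are 95% bootstrap intervals over the members of a list. For none of these patterns can the knockdown be told apart from a batch, since that word stands in the knockdown titles alone, or from a difference in vector or puromycin treatment of the controls, which was not described.

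The first pattern is the lower level of glycolytic and hypoxia-inducible transcripts. Fold changes rose weakly with transcript length (Spearman rho = 0.12 across genes, which are not independent replicates). Length trends within groups were of like size, with rho = 0.12 for control 2 over control 1 and -0.12 for knockdown 2 over knockdown 1. After the length and GC trends were removed, the glycolysis median was still -1.06 (interval -1.52 to -0.64). This argues against these trends as the whole cause, though removing such weak trends could move a median only little. A lower activity of the HIF programme is a candidate explanation that stays open: 25 further hypoxia-inducible genes had a median of only -0.13 (interval -0.58 to -0.01, camera p = 0.0045 and p = 0.087 with an estimated correlation), and this list had been stripped of called genes. A lower MYC programme also stays open. The median of the ribosome biogenesis list was -0.28, and its interval (-0.36 to -0.16) lies on both sides of the bound of -0.3. That bound was set before this list was tested but after the first results were seen. Oxygen, medium age and cell density were not recorded in the labels, so a difference in culture between the groups was not tested.

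The second pattern is the higher level of p53 targets. The median of the list was 0.92 (interval 0.54 to 1.42) after the length and GC trends were removed, which argues against these trends as the whole cause. Here too, removing such weak trends could move the median only little. In 27 further p53 targets the median was 0.58 (interval 0.32 to 0.75) with 21 positive and 0 called, and camera gave p = 9.51e-06, or p = 0.0382 with an estimated correlation and 0.145 when that p was adjusted over the 5 lists. This is consistent with higher p53 activity in the knockdown cells, as a hypothesis. Whether it would follow from the loss of the targeted RNA, from short hairpin expression or from puromycin selection was not tested.

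The third pattern is the higher level of replication-dependent histone transcripts, which was larger in knockdown 2 than in knockdown 1 (833 and 255 CPM in sum). A larger share of cells in S phase could raise the G1/S genes. These were not higher, with a median of -0.36 (interval -0.47 to -0.28). This median was known before the test was chosen, and transcript levels do not count cells in S phase, so the test cannot decide. That interval treats the members as independent, and the list was not called lower with an estimated correlation (adjusted p = 0.60). A carry-over of RNA without a poly(A) tail stays open. The 91 tested genes of small structural RNAs had a median of -0.22 (interval -0.33 to 0.01), but at a median of 1.12 CPM they are close to the detection limit, and many are shorter than the fragments that the library protocol selects. A change in the use of poly(A) sites in histone genes was not tested.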
